A study of Arabidopsis thaliana with 9 samples.

How the data were processed

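RNA was measured in whole Arabidopsis thaliana seedlings of the Col-0 ecotype, kept in darkness for 4 days on agar plates with Murashige and Skoog salts and sucrose. Per the labels, 3 genotypes were compared with 3 biological replicates each: wild type, the mutant cop1-4, and cop1-4 carrying the BBX22-GFPox construct, read here as overexpression of a BBX22-GFP fusion. Biotin-labelled RNA was hybridised to Affymetrix arrays of 1 colour, 1 array per sample. The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, its target intensity and any further filter are not given in the sources used here. The 2% trimmed mean, rounded to whole signal units, was 495 or 496 in all 9 arrays, so the arrays carried a common scaling in the table.

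The table held 22746 probe sets, of which 13513 were paired with 1 gene, 503 with several and 8730 with none in the platform annotation used here. A probe set without a name is unnamed here, not without a gene, and no gene is named from a probe set with several. Of those with 1 gene, 13436 matched a gene table of the TAIR10.1 assembly, which was used only for names and for the order of genes along chromosomes. COP1, BBX22 and HY5 were not analysed here, so the genotypes were not checked against the transcripts of the genes they concern. The table held 0 probe sets with the manufacturer's control prefix, so no ratio of RNA quality was computed.

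Values were transformed as log2(signal + 24.5), the offset being the 20th percentile of all values, which understates changes of dim probe sets. Probe sets whose mean log2 value reached the 30th percentile were kept, leaving 15922, of which 8701 had 1 gene, 329 several and 6892 none. A linear model over the 9 arrays with 1 mean per genotype was fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, and the 3 genotype differences were tested two-sided with Benjamini-Hochberg adjustment within each comparison. A probe set was called at an adjusted p under 0.05, and "rose" and "fell" are used for calls. Means and standard deviations are of the deposited signals, n = 3 arrays. The number of arrays limits the precision. The labels name the replicates biological and say nothing further of separate sowings, so p-values measure the spread between these samples.

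Before the data were examined, the test, the alternatives, the gene lists and the rule for named genes had been fixed. The rule takes, for each of the comparisons cop1-4 against wild type and cop1-4 BBX22-GFPox against cop1-4, the 8 raised and 8 lowered genes of largest change among called probe sets with 1 gene whose 3 arrays of one genotype all lie above the 3 of the other. It takes 4 in each direction for cop1-4 BBX22-GFPox against wild type. It further takes up to 2 raised and 2 lowered called members of each list, or the member of largest change where none is called, and up to 3 genes for each pair of directions among calls shared by both main comparisons. Where a gene had several probe sets, the brightest stood for it.

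The 25 fixed gene lists held 464 members, but the annotation named only 76 probe sets of them, and 22 lists had at least 1 tested member. The 3 lists with at least 5 tested members were tested with camera over 8603 genes with 1 probe set each, with a preset correlation of 0.01. Camera with an estimated correlation and fry were run as alternatives. A further 22 gene families defined by gene symbol were added after the probe annotation had been seen and before any fold change was, and 21 of them had enough members for the set test.

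The labels number the replicates 1 to 3 in every genotype. Deviations from the genotype means correlated between all 9 pairs of same-numbered arrays (r across probe sets 0.375 to 0.806). Deviations cancel within a genotype, so a replicate 1 that stands apart makes those of replicates 2 and 3 correlate without any pairing. Only 4 of the 9 arrays had deviations that correlated best with their own number in both other genotypes. The numbers were taken to pair the samples, though a pairing of replicates 2 and 3 was not shown. A fit with the replicate number as a block is given where it changed a call or moved a count by over 1.5 times. The shared structure lay mostly in replicate 1. Within a genotype, replicates 2 and 3 correlated at 0.982 to 0.989 across probe sets, and replicate 1 with either at 0.816 to 0.926, and replicate 2 of one genotype and replicate 3 of another had deviations that correlated at 0.337 to 0.739. The labels give no scan date or batch. Replicate 1 was therefore treated as a batch, with values within replicate 1 (1 array per genotype, no test) and within replicates 2 and 3 given for the lists tested as sets, the photosynthesis genes and the auxin genes. Fits to replicates 2 and 3 alone and fits with replicate 1 and replicates 2 and 3 as a batch term were chosen after seeing the data. P-values of the fit to replicates 2 and 3 alone measure only the close spread between those arrays. Its calls therefore do not show that a change recurs between batches.

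The other alternatives were no offset, an offset at the 40th percentile (98.2), quantile normalization, scaling to a common median, no filter, a filter at the 50th percentile, eBayes without a trend, array weights, a fit to the compared genotypes alone, an adjusted p under 0.01, a minimum of a 2-fold change, and leaving out each array in turn. The fits without 1 array hold no block. Where the array belongs to a compared genotype, replicate 1 then weighs differently in the genotypes compared. Calls lost or gained in these fits therefore mix the missing array with the difference of replicate 1. The limma fit was tested on simulated data drawn from the real spreads, with 200 of 15922 probe sets changed. For cop1-4 against wild type it recovered 8.96% of 2-fold, 58.2% of 4-fold and 80.3% of 8-fold changes, with 1 false call, and with the block 31.3%, 77.6% and 90.9%, with 4 false calls. For cop1-4 BBX22-GFPox against cop1-4 it recovered 10.4%, 65.7% and 87.9% with 1 false call, and with the block 28.4%, 89.6% and 100% with 10 false calls. For cop1-4 BBX22-GFPox against wild type it recovered 0%, 53.7% and 84.8% with 1 false call, and with the block 17.9%, 83.6% and 93.9% with 8 false calls. Over 50 simulated draws of cop1-4 BBX22-GFPox against cop1-4, camera called 5.33% of unmoved lists and 100% of lists moved by a log2 of 1. In the real data the estimated correlation between members was 0.922 for the flavonoid list, 0.561 for the expansin list and 0.118 for the chlorophyll list. These values come from the fit without a block, whose spread holds the difference of replicate 1. With the replicate block they were 0.554, 0.0142 and 0.0902. In replicates 2 and 3 alone they were 0.209, −0.00245 and −0.0578. The values without a block lie above the preset of 0.01, so the simulated rate of false list calls need not hold for the real lists.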

Results

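Transcript levels were measured on 9 arrays from etiolated seedlings of wild type, cop1-4 and cop1-4 BBX22-GFPox, with 3 arrays per genotype. COP1 encodes an E3 ubiquitin ligase that represses light responses in darkness, and BBX22 is a B-box transcription factor that promotes them. The median signal of the arrays was 182 ± 8.79 (SD, n = 3) in wild type, 167 ± 18.7 in cop1-4 and 172 ± 12.6 in cop1-4 BBX22-GFPox. Exact two-sided permutation tests of these medians gave p = 0.2 for cop1-4 against wild type, p = 0.8 for cop1-4 BBX22-GFPox against cop1-4 and p = 0.2 for cop1-4 BBX22-GFPox against wild type, where 3 arrays against 3 cannot give a p below 0.1. No pair of arrays was a duplicate. Replicate 1 stood apart from replicates 2 and 3 in every genotype, and the first principal component held 46.0% of the variance and the second 35.1%. It did so least in wild type, where it correlated with them at 0.921 to 0.926. The range was 0.816 to 0.819 in cop1-4 and 0.842 to 0.845 in cop1-4 BBX22-GFPox. On the second component the replicate 1 arrays lay at 10.3, 87.9 and 88.3 in the same order. The replicate block takes the same shift for all genotypes, so it need not remove this difference.

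The first comparison asked which transcripts differ between dark-grown cop1-4 and wild type. Of 13 measured photosynthesis genes in 4 lists 8 rose, 1 fell and 4 were not called. Tested as 1 set, which was formed after the probe annotation had been seen, they passed camera (adjusted p = 0.000305), but not with an estimated correlation (adjusted p = 0.614). Their median log2 change was 2.21 in replicate 1 and 0.92 in replicates 2 and 3. All 4 measured photosystem and electron transport subunits rose, by log2 changes of 1.11 to 2.44 (median 2.42 in replicate 1 and 1.25 in replicates 2 and 3). PSAE1 alone of these lost its call without certain arrays (2 of them, adjusted p up to 0.0562 without wild type replicate 1). The photosystem I subunit PSAN (AT5G64040) had a signal of 13910 ± 8466 in cop1-4 against 2271 ± 252 in wild type (SD, n = 3; log2 change 2.44, adjusted p = 0.00349), and the photosystem II subunit PSBY (AT1G67740) rose by a log2 of 1.71. In the Calvin cycle list 2 of 3 members rose (median 2.77 in replicate 1 and 1.12 in replicates 2 and 3), and PRK stood at 0.69 (2.21 and −0.06). RCA (AT2G39730), the Rubisco activase, went from 7215 ± 2142 to 25770 ± 6658 (log2 change 1.85, adjusted p = 0.00339). SBPASE (AT3G55800), a bisphosphatase of the cycle, rose by 1.82 (adjusted p = 0.0148, and 0.0504 without wild type replicate 1). Of 3 antenna members, LHCB4.3 (AT2G40100) rose by 1.86, and LHCB4.2 (AT3G08940) fell from 6481 ± 873 to 2750 ± 2224 (adjusted p = 0.0457). The LHCB4.2 call was lost when any of 7 arrays was left out, with an adjusted p of up to 0.15 without cop1-4 replicate 2, and also with median scaling (0.0944) and with no filter (0.0596). In photorespiration 1 of 3 members was called, GLDT (AT1G11860) of the glycine decarboxylase complex, which rose by 1.19 (adjusted p = 0.0173, lost without any of 3 arrays, up to 0.0616 without wild type replicate 3). All 3 were called with the replicate block. The medians in replicate 1 and in replicates 2 and 3 were 1.93 and 0.89 for photorespiration and 1.18 and 0.53 for the antenna list. Counts adjusted over the list alone were 4 photosystem, 2 Calvin cycle and 2 photorespiration members raised, and 2 antenna members raised and 1 lowered.

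Chlorophyll biosynthesis went both ways. Of 9 members 3 rose, 1 fell and 5 were not called. CHLI2 (AT5G45930), a magnesium chelatase subunit, rose from 480.5 ± 178 to 1356 ± 102 (log2 change 1.52, adjusted p = 0.0161, and 0.0545 without cop1-4 replicate 2), and HEME1 (AT3G14930), a uroporphyrinogen decarboxylase, rose by 1.24. PORB (AT4G27440), a light-dependent protochlorophyllide oxidoreductase, dropped from 12520 ± 3499 to 1838 ± 446 (log2 change −2.74, adjusted p = 0.0014). There were 4 raised and 1 lowered adjusted over the list alone, and with the replicate block 5 were raised and 1 lowered. The list did not pass camera (adjusted p = 0.178, and adjusted p = 0.481 with an estimated correlation) or fry (adjusted p = 0.0714), though fry passed with the block (adjusted p = 0.0245). Its median log2 change was 0.91, with 0.79 in replicate 1 and 0.78 in replicates 2 and 3.

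Called genes of cell expansion and auxin response, 2 of 8 and 2 of 4, were all lower in cop1-4. All 8 measured expansins and xyloglucan endotransglucosylases, enzymes and proteins that loosen cell walls, had negative log2 changes (median −1.72). Only 2 of them fell, both expansins, and no xyloglucan endotransglucosylase was called. EXPA4 (AT2G39700) dropped from 2127 ± 385 to 480.5 ± 87.5 (log2 change −2.09, adjusted p = 0.00574). EXPA8 (AT2G40610) fell by 2.06 (adjusted p = 0.0364, lost without any of 5 arrays, up to 0.0986 without wild type replicate 3). The count adjusted over the list alone was also 2. The list as a whole missed the threshold in camera (adjusted p = 0.0607). It also missed it with an estimated correlation (adjusted p = 0.481) and in fry (adjusted p = 0.0714). With the replicate block 5 members were lowered and the list passed camera (adjusted p = 0.0116) and fry (adjusted p = 0.00276), but not with an estimated correlation (adjusted p = 0.139). Its median was −1.90 in replicate 1 and −1.26 in replicates 2 and 3, and 7 of the 8 genes were themselves lower in replicate 1 than in replicates 2 and 3 across the genotypes. Without wild type replicate 1 the adjusted p was 0.0102, without cop1-4 replicate 2 it was 0.0202, without cop1-4 replicate 3 it was 0.0207, and without cop1-4 BBX22-GFPox replicate 1 it was 0.047.

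Of 4 auxin genes, too few for a set test here, 2 fell, also when adjusted over the list alone (median −2.50 in replicate 1 and −1.06 in replicates 2 and 3). IAA20 (AT2G46990), an Aux/IAA repressor, went from 524 ± 139 to 60.0 ± 7.77 (log2 change −2.67, adjusted p = 0.00186), and GH3.5 (AT4G27260), which conjugates auxin to amino acids, fell by 2.55. The gibberellin receptor gene GID1B (AT3G63010) fell by 1.16, the other member of the gibberellin and brassinosteroid list was not called. One of 2 heat shock genes fell (HSP22, AT4G10250, log2 change −1.73), as did 1 of 4 cold and abscisic acid genes (the dehydrin gene COR47, AT1G20440, log2 change −0.98). Of 2 seed maturation genes the oleosin gene OLEO3 (AT5G51210) fell by 4.69, from 2143 ± 182 to 59.8 ± 12.5. In light signalling, FHL (AT5G02200), which acts in phytochrome A import into the nucleus, fell by 1.27 (adjusted p = 0.0288), and the other of 2 members was not called. The FHL call was lost with quantile normalization (0.0536), with median scaling (0.0649) and without any of 5 arrays (up to 0.0932 without wild type replicate 1). Adjusted over the list alone, light signalling had 1 member raised and 1 lowered, cold and abscisic acid 1 raised and 1 lowered, and the gibberellin, heat shock and seed maturation lists 1 lowered each.

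In the flavonoid and anthocyanin list only 1 of 8 members was called, UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, which rose by 1.68 (adjusted p = 0.0353, lost without any of 6 arrays, up to 0.114 without wild type replicate 1). None was called adjusted over the list alone (0, where 2 had an unadjusted limma p under 0.05), and 2 were called with the replicate block. The list's median change was −0.02 and turned to 0.05 with median scaling, while its mean was 0.39 and its camera direction upward (adjusted p = 0.424). The median was 0.13 in replicate 1 and 0.15 in replicates 2 and 3, and all 8 genes were lower in replicate 1 than in replicates 2 and 3 across the genotypes.

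No member of the remaining lists with tested genes was called, apart from TIP41 (AT4G34270) among 4 reference genes. TIP41 rose by 0.83 (adjusted p = 0.0197, lost without any of 4 arrays, up to 0.0737 without wild type replicate 2). The lycopene cyclase gene LYC had a log2 change of 0.56 (adjusted p = 0.147, and 0.019 with the replicate block). The ethylene regulator EIN3 stood at −0.66 (0.292, block 0.0416), isocitrate lyase, ICL, of seed oil mobilisation at −1.94 (0.11, block 0.0115), the root hair expansin EXPA7 at 1.21 (0.301, block 0.0186) and the guard cell regulator FAMA at 0.91 (0.0644, block 0.0114). The replication gene MCM7 stood at 0.46 (0.566) and the leaf polarity gene YAB3 at 0.11 (0.743). The clock gene GI stood at −0.06 (0.936) and changed sign under quantile normalization and median scaling. Adjusted over the list alone, 1 stomatal gene and 1 reference gene were raised. With the replicate block the calls were 2 lowered in seed oil mobilisation, 2 raised among root hair markers, 2 raised among reference genes, 2 lowered in the cold list, 2 raised and 1 lowered in the antenna list and 1 raised and 1 lowered in light signalling. The B-box, defence and root endodermis lists had no tested member.

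Among named genes of largest change, the thionin gene THI2.2 (AT5G36910) rose from 7.53 ± 0.231 to 3125 ± 1185 (log2 change 6.56, SE 0.479, adjusted p = 0.000185). AT2G25510 rose by 5.36, AT5G55450 by 5.17, AT5G04380 by 4.58, AT4G34950 by 4.29, AT1G70820 by 4.11 and AT1G51110 by 3.94, and AT3G57020 rose from 84.2 ± 31.9 to 2030 ± 1329. The AT5G04380 call was lost without any of 4 arrays (adjusted p up to 0.0719 without wild type replicate 1). Among the lowered genes AT4G07820 fell from 7835 ± 4759 to 47.8 ± 10.0. AT5G45500 went from 2396 ± 109 to 8.70 ± 0.520 (log2 change −6.19, adjusted p = 4.6e-07). The wild type signal of THI2.2 and the cop1-4 signal of AT5G45500 lay under the offset of 24.5, so their log2 changes are compressed and give no order among these genes. AT5G44440 fell by 6.17, ZW9 (AT1G58270) fell by 5.77 and OCT1 (AT1G73220), an organic cation transporter gene, had a log2 change of −5.08. AT4G22490 fell by 4.35 and AT1G20390 fell by 3.97.

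In all, limma called 4100 of 15922 probe sets, 1795 raised and 2305 lowered, and 2984 of them changed at least 2-fold. The replicate block called 7096, including all 4100, and replicates 2 and 3 alone gave 9932. Median scaling moved the median log2 change of all probe sets from −0.11 to 0.01, a shift of 0.12, and turned the split of calls to 2294 raised and 1733 lowered, so directions hold relative to the common scaling. The count fell to 2526, 2441 and 2279 without wild type replicates 1, 2 and 3, and to 2214 and 2636 without cop1-4 replicates 2 and 3.

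**Figure D1:**
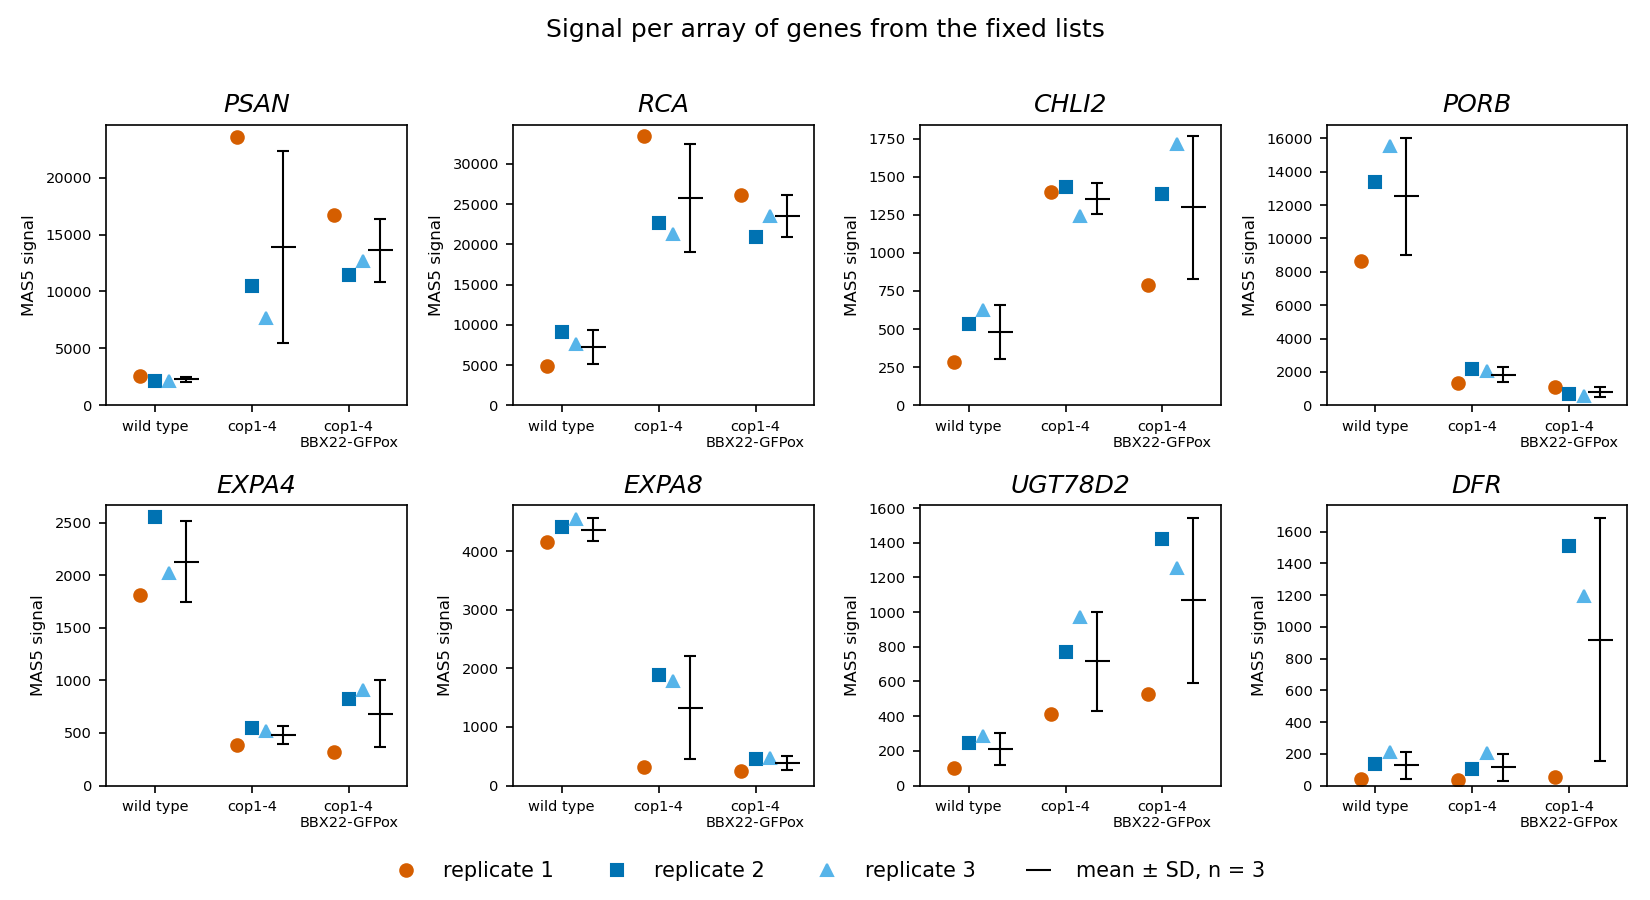
MAS5 signal (vertical axis, linear, from 0) of PSAN, RCA, CHLI2, PORB, EXPA4, EXPA8, UGT78D2 and DFR on each of the 9 arrays, by genotype, with markers and colours for replicates 1, 2 and 3 and black dashes for the mean with bars of 1 SD (n = 3). PSAN had a mean of 2271 in wild type and 13910 in cop1-4, PORB one of 12520 and 1838, and UGT78D2 and DFR were lower in replicate 1 than in replicates 2 and 3.

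The second comparison asked what BBX22-GFPox changed in the cop1-4 background. Few transcripts were called over all arrays, 45 higher and 3 lower with the construct. AT1G23130 rose from 34.6 ± 19.7 to 1404 ± 71.7 (SD, n = 3; log2 change 4.65, adjusted p = 0.000225). AT5G45500 rose from 8.70 ± 0.520 to 779 ± 47.8 (log2 change 4.60, adjusted p = 6.23e-06), ZW9 from 51.7 ± 0.872 to 1672 ± 110 (4.47, adjusted p = 5.36e-05) and AT2G01090 from 32.1 ± 19.7 to 835 ± 187 (3.97, adjusted p = 0.00154). These 4 kept their call when any 1 array was left out. Limma called 48 of 15922 probe sets, 45 raised and 3 lowered, and 1194 had an unadjusted p under 0.05. The replicate block called 206, 165 raised and 41 lowered, and replicates 2 and 3 alone gave 3856 calls, each including all 48. The split was close to even in replicates 2 and 3 alone (2023 raised, 1833 lowered), with array weights (1878 and 1632) and without cop1-4 replicate 1 (207 and 165).

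The next raised genes were AT5G44520 (log2 change 3.57, adjusted p = 0.00733), AT4G07820 (3.27, 0.0449), AT5G16980 (3.25, 0.00781) and AT4G02540 (3.11, 0.00842). Each lost its call without certain arrays: AT5G44520 without either of 2 arrays (up to 0.0564 without cop1-4 BBX22-GFPox replicate 3), AT4G07820 without any of 7 (up to 0.242 without cop1-4 BBX22-GFPox replicate 3), AT5G16980 without cop1-4 BBX22-GFPox replicate 2 (0.0629) and AT4G02540 without any of 3 (up to 0.0712 without cop1-4 BBX22-GFPox replicate 2). AT4G07820 was also lost with the larger offset (0.116), quantile normalization (0.0572) and the filter at the 50th percentile (0.0589), and AT5G16980 with no offset (0.0851). AT1G12080 fell from 4550 ± 1228 to 1056 ± 116 (log2 change −2.05, adjusted p = 0.0221) and AT3G42800 fell by 1.72 (0.0223). Each was lost without any of 6 arrays (up to 0.14 without cop1-4 BBX22-GFPox replicate 3 for AT1G12080, and up to 0.156 without cop1-4 BBX22-GFPox replicate 2 for AT3G42800). The third lowered probe set has no name here.

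The flavonoid and anthocyanin genes were higher with BBX22-GFPox as a list. All 8 members had positive log2 changes (median 1.49) and the list passed camera (p = 0.00155, adjusted p = 0.00464), but not with an estimated correlation (adjusted p = 0.626) or in fry (adjusted p = 0.473). No single member was called by limma, over all probe sets or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The replicate block called 1. The largest change was that of DFR (AT5G42800), a dihydroflavonol reductase of anthocyanin synthesis, at 114 ± 85.3 in cop1-4 and 919 ± 764 with the construct (log2 change 2.16, adjusted p = 0.771). The list's median difference was 0.42 in replicate 1 and 1.54 in replicates 2 and 3. In replicates 2 and 3 alone all 8 members were called, where p-values measure only the spread between those arrays. All 8 genes were lower in replicate 1 than in replicates 2 and 3 across the genotypes. The list call was lost without cop1-4 replicate 1 (adjusted p = 0.296) and without cop1-4 BBX22-GFPox replicate 2 (0.151) or 3 (0.17). These fits hold no block, so they weigh replicate 1, where the list was lower (median −2.45), differently in the compared genotypes.

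**Figure D2:**
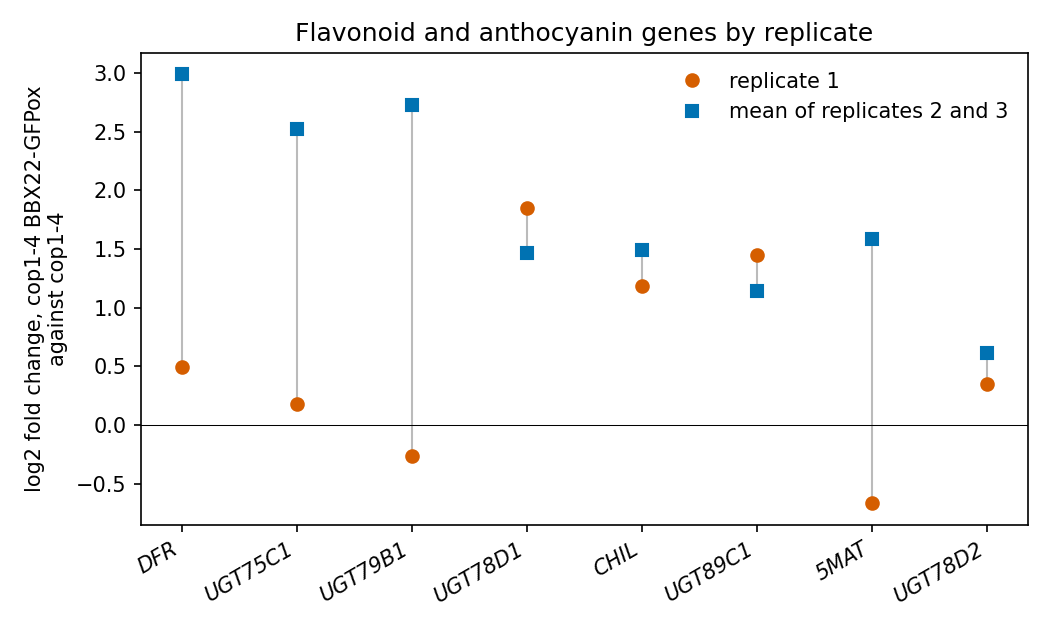
Log2 difference between cop1-4 BBX22-GFPox and cop1-4 for the 8 flavonoid and anthocyanin genes, in replicate 1 (orange circles) and as the mean of replicates 2 and 3 (blue squares). The median was 0.42 in replicate 1 and 1.54 in replicates 2 and 3, and 6 of the 8 genes had the larger difference in replicates 2 and 3.

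Over all arrays the genes of light-driven greening that separated cop1-4 from wild type were not called between cop1-4 BBX22-GFPox and cop1-4. Across all 69 tested list genes limma called 0, with 9 at an unadjusted p under 0.05, and the replicate block called 2. In replicates 2 and 3 alone 19 of them were raised, 8 of these in the flavonoid list, and 11 lowered. One of the block's calls was LHCB4.2, with a log2 change of 1.84 (adjusted p = 0.231, and 0.0445 with the block). PSAN stood at 0.12 (adjusted p = 0.999), PRK of the Calvin cycle at 0.53 (0.999), the photorespiratory gene HPR1 at 0.82 (0.988), PORB at −1.24 (0.274) and LYC at 0.18 (0.999). The HY5 homolog HYH (AT3G17609) stood at 1.19 (0.233), GID1B at 0.83 (0.283), HSP22 at −0.78 (0.42) and ICL at 1.70 (0.73). The auxin gene GH3.3 had a signal of 316 ± 200.2 in cop1-4 and 79.0 ± 8.91 with the construct (0.496). All 4 auxin genes had negative log2 changes, with a median of 0.45 in replicate 1 and −1.01 in replicates 2 and 3, where 3 were lowered. EXPA8 stood at −1.41 (0.64), GI at 0.12, EIN3 at 0.25, OLEO5 at 0.30, MCM7 at −0.36, EXPA18 at −0.37, the stomatal gene SPCH at 0.56, YAB3 at 0.14 and TIP41 at −0.24, each with an adjusted p of at least 0.64. The cold and abscisic acid list had no called member. Adjusted over the list alone, 1 member was raised in each of the antenna, light signalling and gibberellin lists, 1 was lowered in the heat shock list and 2 in the cold and abscisic acid list, and 0 in the others. The 13 photosynthesis genes had a median of −0.20 in replicate 1 and 0.32 in replicates 2 and 3, and as a set they did not pass camera (adjusted p = 0.515). Without cop1-4 replicate 1 the set passed (adjusted p = 0.00867), as it did in replicates 2 and 3 alone (adjusted p = 0.0215, but adjusted p = 0.736 with an estimated correlation). Camera did not call the chlorophyll list (median −0.13, −0.19 in replicate 1 and 0.05 in replicates 2 and 3, adjusted p = 0.364, and 0.626 with an estimated correlation). It did not call the expansin list either (median −0.05, adjusted p = 0.383, and 0.698 with an estimated correlation), which passed without cop1-4 replicate 1 (adjusted p = 0.0363). Without that array, replicate 1 is left in only 1 of the compared genotypes. Replicate 1 differed for both sets across the genotypes (median 0.41 for the photosynthesis genes and −1.155 for the expansin list). The expansin median was 0.11 in replicate 1 and −0.28 in replicates 2 and 3, where the list passed (adjusted p = 0.0294), but not with an estimated correlation (adjusted p = 0.142). The total of 48 fell to 21 and 22 without wild type replicates 2 and 3, to 18 without either of cop1-4 replicates 2 and 3, and to 11 and 12 without cop1-4 BBX22-GFPox replicates 2 and 3, and rose to 372 without cop1-4 replicate 1 and to 130 without cop1-4 BBX22-GFPox replicate 1.

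The genes raised in cop1-4 BBX22-GFPox against cop1-4 were set against those that differ between cop1-4 and wild type. Of the 45 raised probe sets, 39 had fallen in cop1-4 against wild type, where independent lists of these sizes would share 6.51. AT5G45500 fell by 6.19 and then rose by 4.60, ZW9 fell by 5.77 and rose by 4.47, and AT2G01090 fell by 3.71 and rose by 3.97. Lower levels in cop1-4 than in wild type were seen for 44 of the 45. Their median log2 change was −2.14 from wild type to cop1-4, 2.22 from cop1-4 to cop1-4 BBX22-GFPox and −0.0018 between cop1-4 BBX22-GFPox and wild type, where 28 of the 45 were not called, 7 were lowered and 10 raised. Calls in the same direction in both comparisons were 2 lowered (0.434 for independent lists), of which AT1G12080 has a name here (log2 changes −1.52 and −2.05), and 1 raised (5.07), without a name here. Raised and then lowered were 0, where limma's block fit gave 16.

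The 2 comparisons share the 3 cop1-4 arrays, which pushes their fold changes in opposite directions with no effect at all. With 100 simulated sets of unchanged genotypes, at most 1 call was shared. These sets hold no difference between cop1-4 and wild type, so little could be shared in them. They cannot tell whether the observed overlap exceeds the noise of the shared arrays. Across the 15922 probe sets, which are not independent replicates, the fold changes correlated at −0.305 against −0.50 in the simulations. The covariance was −0.137 against a simulated −0.102, a difference of −0.035. The 3 control arrays cannot be split into parts of 2, so part of the excess may come from the shared arrays. With the replicate block 162 calls were shared, 126 of them lowered and then raised (40.6 for independent lists), 12 raised in both (32.9) and 8 lowered in both (10.1), and the simulated covariance was −0.0439. In replicates 2 and 3 alone 2959 were shared, 1216 of them lowered and then raised. The 42 shared calls became 18 and 19 without wild type replicates 2 and 3, 256 without cop1-4 replicate 1, 17 without cop1-4 replicate 2 or 3, and 110, 10 and 11 without cop1-4 BBX22-GFPox replicates 1, 2 and 3.

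**Figure D3:**
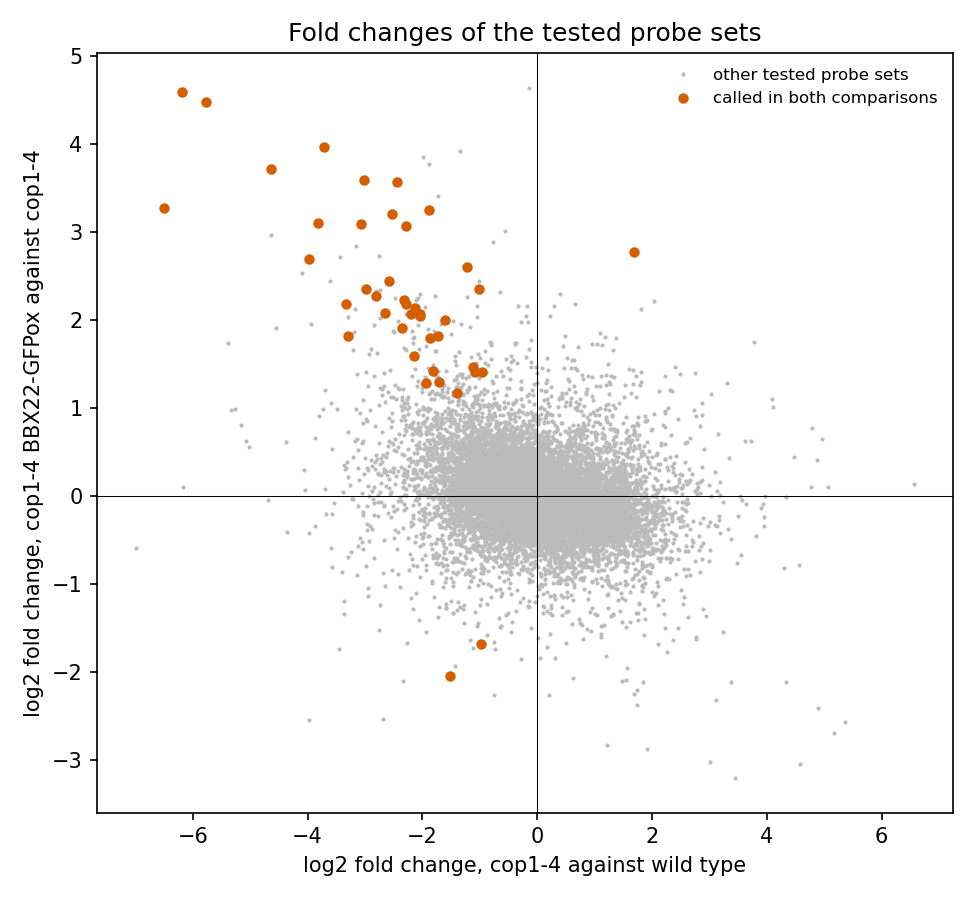
Log2 change of cop1-4 against wild type (horizontal axis) and of cop1-4 BBX22-GFPox against cop1-4 (vertical axis) for each of the 15922 tested probe sets (grey), with the 42 called in both comparisons in orange. Of these, 39 lie at the upper left, lowered in cop1-4 and raised with BBX22-GFPox, and both axes share the 3 cop1-4 arrays.

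The third comparison set cop1-4 BBX22-GFPox against wild type. All 4 photosystem subunits rose again, PSAN to 13610 ± 2740 against 2271 ± 252 (SD, n = 3; log2 change 2.56, adjusted p = 0.00318) and PSBY by 1.80, though PSAE1 lost its call without any of 6 arrays (up to 0.0928 without cop1-4 BBX22-GFPox replicate 3). SBPASE rose by 1.97 and RCA by 1.74, 2 of 3 Calvin cycle genes, while PRK stood at 1.22 (adjusted p = 0.151, and 0.0429 with the replicate block). The medians in replicate 1 and in replicates 2 and 3 were 2.24 and 1.41 for the photosystem, 2.42 and 1.41 for the Calvin cycle and 0.71 and 0.67 for the antenna list, and the photorespiration gene GLDT had values of 1.79 and 1.23. As 1 set the 13 photosynthesis genes passed camera (9 raised, adjusted p = 7.72e-06), but not with an estimated correlation (adjusted p = 0.425). All 4 auxin genes fell, with log2 changes of −2.80 for GH3.5 and −2.79 for IAA20 (median −2.25 in replicate 1 and −2.24 in replicates 2 and 3). HYH went from 115 ± 37.9 to 549.9 ± 179 (log2 change 2.03, adjusted p = 0.00311), while FHL fell by 1.75.

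Of 9 chlorophyll genes 3 rose and 1 fell. HEME1 rose by 1.06 and CHLI2 by 1.39 (adjusted p = 0.0247, lost without any of 4 arrays, up to 0.0921 without cop1-4 BBX22-GFPox replicate 3), and PORB fell to 782 ± 290 (log2 change −3.98, adjusted p = 0.00033). The list did not pass camera (adjusted p = 0.158, and 0.39 with an estimated correlation) or fry (adjusted p = 0.229), though fry passed with the block (adjusted p = 0.0418). Its median was 0.62 in replicate 1 and 0.74 in replicates 2 and 3. Of 3 photorespiration genes 2 rose, HPR1 by 2.57 (adjusted p = 0.0283, lost without any of 6 arrays, up to 0.0899 without wild type replicate 3) and GLDT by 1.42. In the antenna list only LHCB4.3 rose (1.23, adjusted p = 0.0268, lost without any of 5 arrays, up to 0.0996 without cop1-4 BBX22-GFPox replicate 3). FAMA rose by 1.24 (adjusted p = 0.0259, lost without any of 5 arrays, up to 0.077 without cop1-4 BBX22-GFPox replicate 2), 1 of 2 stomatal genes. HSP22 (−2.51), COR47 (−1.54) and OLEO3 (−4.74) fell, each the only called member of its list.

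The flavonoid list passed camera (adjusted p = 0.022) with all 8 log2 changes positive (median 1.42), but not with an estimated correlation (adjusted p = 0.39) or in fry (adjusted p = 0.223, and 0.00291 with the replicate block). CHIL (AT5G05270), a chalcone isomerase-like protein gene, rose by 3.88 (adjusted p = 0.0353, lost without any of 5 arrays, up to 0.121 without cop1-4 BBX22-GFPox replicate 3) and UGT78D2 from 210.1 ± 94.4 to 1069 ± 475 (adjusted p = 0.0145, lost without either of 2 arrays, up to 0.0577 without cop1-4 BBX22-GFPox replicate 3). The other members were not called, and 4 were called in all with the replicate block. The median was 0.02 in replicate 1 and 2.21 in replicates 2 and 3, and all 8 genes were lower in replicate 1 across the genotypes. The list call was lost without wild type replicate 1 (adjusted p = 0.0841) and without cop1-4 BBX22-GFPox replicate 2 (0.0869) or 3 (0.0886). These fits, too, hold no block and weigh replicate 1 differently in the compared genotypes.

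The expansin and xyloglucan endotransglucosylase list also passed camera (adjusted p = 0.0194, median −1.92), but not with an estimated correlation (adjusted p = 0.39) or in fry (adjusted p = 0.0779, and 0.00176 with the replicate block). Of its 8 members 3 fell, EXPA8 (log2 change −3.47) and XTH33 (AT1G10550, −2.24, adjusted p = 0.0256, lost without any of 4 arrays, up to 0.0926 without wild type replicate 3) among them, and 5 fell with the replicate block. The median was −1.86 in replicate 1 and −1.62 in replicates 2 and 3, and 7 of the 8 were lower in replicate 1 across the genotypes. Adjusted over the list alone, the calls of the lists were the same in number except for 4 chlorophyll genes, 2 antenna genes, 2 stomatal genes, 2 reference genes and 1 carotenoid gene raised. With the replicate block 5 chlorophyll, 3 Calvin cycle, 3 photorespiration, 2 antenna, 2 stomatal and 2 reference genes were raised.

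Not called were LYC (0.74, adjusted p = 0.0788, and 0.00699 with the replicate block), the lipase gene SDP1 (−0.67, 0.516, block 0.0413) and the reference gene AT4G26410 (0.79, 0.0648, block 0.0246). The same held for GI (0.06, 0.936), GID1B (−0.33, 0.337), EIN3 (−0.41, 0.535), MCM7 (0.10, 0.913), EXPA7 (0.92, 0.452) and YAB3 (0.25, 0.448). The genes of largest change were THI2.2, which rose by 6.70, the methionine sulfoxide reductase gene MSRB6 (AT4G04840) by 5.54, AT3G57020 by 5.20 and AT1G70820 by 5.12, and the pectin methylesterase gene ATPMEPCRD (AT2G43050), which went from 15840 ± 3410 to 152 ± 58.4 (log2 change −6.51, adjusted p = 0.00016), AT5G44440 (−6.07) and AT4G22490 (−4.77). Limma called 3427 of 15922 probe sets, 1561 raised and 1866 lowered, 2504 of them at least 2-fold, the replicate block called 6479, including all 3427, and replicates 2 and 3 alone gave 9590. The count fell to 2159, 1994 and 1836 without wild type replicates 1, 2 and 3, and to 1859 and 1819 without cop1-4 BBX22-GFPox replicates 2 and 3.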

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

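The fits to replicates 2 and 3 alone and the fits with replicate 1 as a batch term were chosen after seeing the data. The other alternatives were set beforehand, and those for COP1 and BBX22 were not run, since these genes were not analysed here. Of 116 named values, 77 were called, and 0 of those changed direction under any alternative. Offsets, scalings, filters and the variance model lost at most 2 of these each (the filter at the 50th percentile left 97 values tested), and leaving out 1 array lost up to 15. Why array weights and the treatment of replicate 1 moved the counts so far was not tested, and neither were the other causes, except that the filter at the 50th percentile tests fewer probe sets and a fit to the compared genotypes alone or without an array holds fewer arrays. Fits without 1 array also hold no block and leave replicate 1 unevenly weighed between the genotypes. Signals under the offset of 24.5 made up at least 18.3% of each array, and fold changes involving them are compressed.

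The count of 4100 calls in cop1-4 against wild type became 7096 with the replicate block, 7910 with replicate 1 as a batch term, 9932 in replicates 2 and 3 alone, 9776 with array weights and 1535 at an adjusted p under 0.01. Without 1 array it ranged from 2214 (without cop1-4 replicate 2) to 5641 (without cop1-4 replicate 1). The 3427 calls in cop1-4 BBX22-GFPox against wild type became 6479 with the block, 7250, 9590, 9389 and 1323 in the same order, and 1819 (without cop1-4 BBX22-GFPox replicate 3) to 4820 (without cop1-4 replicate 1).

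The 48 calls in cop1-4 BBX22-GFPox against cop1-4 became 206 with the replicate block, 432 with replicate 1 as a batch term, 3856 in replicates 2 and 3 alone, 3510 with array weights, 18 at an adjusted p under 0.01, 27 with the filter at the 50th percentile and 14 with only the 2 genotypes compared. Without 1 array they ranged from 11 (without cop1-4 BBX22-GFPox replicate 2) to 372 (without cop1-4 replicate 1). The 42 calls shared by both main comparisons became 162 with the block, 333, 2959, 2535, 16 and 23 in the same order of the first 6 alternatives, and 10 (without cop1-4 BBX22-GFPox replicate 2) to 256 (without cop1-4 replicate 1).

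Of the 3 tested lists, camera called 0 in cop1-4 against wild type (1 at an unadjusted p under 0.05), and so did fry (2 at an unadjusted p under 0.05). Camera called 1 with quantile normalization, median scaling, array weights, the replicate block, replicate 1 as a batch term or replicates 2 and 3 alone. With no filter it called 2, the expansin list and a further list that had too few tested members under the filter. Without 1 array it called 0 to 1 (1 without wild type replicate 1, cop1-4 replicate 2, cop1-4 replicate 3 or cop1-4 BBX22-GFPox replicate 1). In cop1-4 BBX22-GFPox against cop1-4 it called 1, which became 2 in replicates 2 and 3 alone, 0 with an estimated correlation and in fry, and 0 to 1 without 1 array (0 without cop1-4 BBX22-GFPox replicate 2 or 3, and without cop1-4 replicate 1 the expansin list in place of the flavonoid list). In cop1-4 BBX22-GFPox against wild type it called 2, which became 0 with an estimated correlation and in fry and 1 to 2 without 1 array (1 without wild type replicate 1 or cop1-4 BBX22-GFPox replicate 2 or 3). No list call held with an estimated correlation. With the block fry called 2 lists in cop1-4 against wild type and 3 in cop1-4 BBX22-GFPox against wild type. The replicate block changed no call of a list or named gene other than those given beside them.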

Other observations

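All tests weighed in this part were chosen only after the results they bear on had been seen, and the gene families after the probe annotation had been. The genes named from the families were chosen after their values were seen.

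Some genes encoded in the plastid genome rose in cop1-4. Of 33 probe sets for plastid-encoded photosynthesis subunits 8 rose, 0 fell and 32 had positive log2 changes (median 0.63, 0.96 in replicate 1 and 0.57 in replicates 2 and 3), and the family passed camera (adjusted p = 0.000305, and adjusted p = 0.614 with an estimated correlation). The photosystem II reaction centre gene psbA went from 759.6 ± 550.2 to 6443 ± 5988 (SD, n = 3; log2 change 2.87, adjusted p = 0.0329, lost without any of 4 arrays, up to 0.108 without wild type replicate 3), psbZ rose by 1.27 and psaJ rose by 1.02, and of the 8 raised psbZ and psaJ alone kept their call without any 1 array, while rbcL, the large Rubisco subunit gene, stood at −0.49 (adjusted p = 0.217). The replicate block called 17 of the 33, and without cop1-4 replicate 1 the family missed the threshold (adjusted p = 0.0624). The plastid NDH subunits (1 of 10 raised, 6 with the block, camera adjusted p = 0.0485) and the plastid ribosomal protein and RNA polymerase genes (1 of 19 raised, 3 with the block, 0.0485) also passed, and neither did with an estimated correlation (adjusted p = 0.614). Both also missed it with quantile normalization (0.151 and 0.197), with median scaling (0.0898 and 0.0653) and without wild type replicate 2 (0.138 for both), wild type replicate 3 (0.0872 and 0.091) or cop1-4 replicate 1 (0.387 and 0.138), and the second also without cop1-4 replicate 3 (0.0962). The raised ribosomal gene, rps2, lost its call without any of 4 arrays (up to 0.0762 without wild type replicate 3). Arrays of this kind are usually labelled from poly(A) tails, so levels of plastid transcripts depend on the labelling as well.

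Members of cell wall and membrane families fell in cop1-4. Of the 21 tested families, 7 passed camera in cop1-4 against wild type, and 0 did with an estimated correlation. The whole expansin family includes EXPA4 and EXPA8, which were already called in the fixed list. In the whole expansin family, with 13 members tested, 7 fell (camera adjusted p = 0.0166, and adjusted p = 0.614 with an estimated correlation), EXPA9 among them, from 3326 ± 465 to 485 ± 87.2 (SD, n = 3; log2 change −2.72, adjusted p = 0.000195). Of 16 TBL genes, which encode proteins acting in wall polysaccharide acetylation, 5 fell (adjusted p = 0.0166, and adjusted p = 0.614 with an estimated correlation), TBL38 from 1299 ± 351 to 154 ± 95.4 (log2 change −3.03), and 8 fell with the replicate block. Of 8 tetraspanin genes 6 fell (adjusted p = 0.0211, and adjusted p = 0.547 with an estimated correlation), with log2 changes of −1.33 for TET7 and −1.25 for TET2. Without cop1-4 replicate 1 these families gave an adjusted p of 0.0505, 0.0624 and 0.0505. EXPA20 and EXPA8, TBL25, and TET4, TET3 and TET8 lost their calls without certain arrays (adjusted p up to 0.146, for TET4 without wild type replicate 1). The whole xyloglucan endotransglucosylase family, with 8 members tested, did not pass camera in cop1-4 against wild type. Its median log2 change was −0.43, and no member was called. The bZIP factors missed the threshold (adjusted p = 0.0527) and passed with the replicate block (0.0437), but not with the block and an estimated correlation (adjusted p = 0.4), and did the same in cop1-4 BBX22-GFPox against wild type (0.0536, 0.041 and 0.347). Median log2 changes of expansins, TBL genes and tetraspanins were −1.18, −0.74 and −1.14 in replicate 1 and −1.13, −0.74 and −1.04 in replicates 2 and 3. In cop1-4 BBX22-GFPox against wild type, 3 of 9 GH9 endoglucanases fell too (adjusted p = 0.0225, adjusted p = 0.553 with an estimated correlation, and 0.0634 without cop1-4 BBX22-GFPox replicate 1), GH9B13 from 2295 ± 558 to 95.9 ± 78.6 (log2 change −4.56), and 6 fell with the replicate block. Between cop1-4 BBX22-GFPox and cop1-4 camera called 0 of the 21 families (3 at an unadjusted p under 0.05 and 0 in fry). The plastid-encoded photosynthesis subunits passed there with the replicate block (adjusted p = 0.0161), with quantile normalization (0.0214) and without cop1-4 replicate 1 (0.000722) or cop1-4 BBX22-GFPox replicate 2 (0.00277) or 3 (0.014). Ubiquitin-conjugating enzymes passed with the block (0.0161), with quantile normalization (0.0299) and without cop1-4 replicate 2 (0.0284) or cop1-4 BBX22-GFPox replicate 1 (0.0115). With the block and an estimated correlation neither family passed (adjusted p = 0.722 and adjusted p = 0.623). Glutathione S-transferases (0.0115) and TBL genes (0.0299) passed without cop1-4 BBX22-GFPox replicate 1, and the nuclear photosynthesis genes as 1 set without cop1-4 replicate 1 (0.00867).

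Replicate 1 differed from replicates 2 and 3 in every genotype, with 7041 probe sets called between them, 2997 higher and 4044 lower in replicate 1. Array scaling and a different distribution of values are argued against by the count of 7024 called after quantile normalization (the overlap with the 7041 was not counted). Seedlings at an earlier stage in replicate 1 are a candidate explanation. A set of 6 seed-phase genes had a median log2 difference of 1.68 (0.23 to 2.47, 5 raised). OLEO3, OLEO5, ICL and SDP1 came from the fixed lists. The LEA genes AT5G06760 and AT2G21490 were added after other changes in replicate 1 had been seen. The 2 root hair markers, which appear later, had a median of −2.44 and were both lower. The same values could come from a difference in growth or sowing other than stage, which stays untested. No prediction was set for other lists that differed. Of 33 plastid-encoded photosynthesis subunits 21 were higher and 0 lower, and of 13 nuclear photosynthesis genes 6 were higher and 0 lower. All 8 flavonoid genes were lower (median −2.45). No biological explanation from the design applies, since all replicates of a genotype carry the same labels.

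Probe sets higher in cop1-4 BBX22-GFPox than in cop1-4 were mostly those lower in cop1-4 than in wild type (39 of 45), and probes shared between paralogs are argued against by the 6.67% of the 45 with a suffix for shared probes (3.59% of all tested). Noise of the shared cop1-4 arrays stays open: simulations without change shared at most 1 call but draw noise independently per probe set, and of 1971 probe sets raised in replicates 2 and 3 (with the block) 51.3% lay below wild type in cop1-4 of replicate 1, against 75.5% of 518 in the opposite parting (all probe sets 55.9% and 53.8%, and partings of the cop1-4 arrays alone 51.9% to 94.4%, with at least 10 probe sets each). Genome segments that differ between the lines are a candidate explanation: among 25 raised loci, 3 pairs lay within 20 genes of each other (AT5G44520 and AT5G44530, AT5G51620 and AT5G51630, AT5G45410 and AT5G45500), against a mean of 0.363 in random draws (p = 0.006, permutation test with 10000 draws) or 0.372 in draws from loci lowered in cop1-4 (p = 0.0062). With the replicate block 11 pairs were found among 83 loci (p = 0.0048, permutation test), but the draws do not model neighbouring genes that are co-regulated, so these cannot be separated here. Of the 25 loci, 12 lay on chromosome 5, which held all 3 pairs and 2039 of the 8500 tested loci. On chromosome 3, with 1744 tested loci, the count was 0. With the block 27 of the 83 loci lay on chromosome 5 and 37 on chromosome 1, which held 2220 tested loci. An effect of BBX22 on transcripts lowered in cop1-4, the explanation the design names, stays open and untested.

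The flavonoid list was higher with BBX22-GFPox mainly in replicates 2 and 3 (median 1.54 against 0.42 in replicate 1), and the median of the differences between them was 1.28. A shift of all genes in replicate 1 is argued against by the list's place at percentile 100 among 10000 random lists (95th percentile 0.296). Compression of low signals by the offset may account for part of it: with no offset the medians were 1.05 in replicate 1 and 1.74 in replicates 2 and 3, which leaves it open. The difference was larger in replicates 2 and 3 for 6 of the 8 members. Replicate 1 has 1 array per genotype, so its spread is unknown. A test between replicate 1 and the others cannot decide whether the effect of the construct differs between them. A response to BBX22 that depends on how far the seedlings had developed stays untested.

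Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split alone (1 of 10) gave as many calls as observed in cop1-4 against wild type (4100, highest other 0), in cop1-4 BBX22-GFPox against cop1-4 (48, highest other 0) and in cop1-4 BBX22-GFPox against wild type (3427, highest other 0). Every other split, with or without the block, holds arrays of both genotypes on each side. Any difference between the genotypes then widens the spread and lowers the count. The counts of 0 therefore do not show what unchanged genotypes would give. At an unadjusted limma p under 0.05 the other splits reached 1630, 4776 and 1245 probe sets. The 4776 exceed the 1194 of the real split and came from a split that puts both replicate 1 arrays on one side, a structure of the samples, while in the real split the replicate block gives 206 calls. Among the 4 splits that part all 3 pairs of replicate numbers, the block fit gave 7096, 206 and 6479 calls in the real split and at most 0 in the others, which exchange the arrays of 1 pair.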
